A study of Oryza sativa Indica Group with 4 samples.

How the data were processed

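RNA from panicle primordia was labelled with biotin and hybridised to an Affymetrix rice array by the submitters, per the labels' protocols. The deposited table holds 1 intensity value per probe set and array on a linear scale. GCOS 1.2, Affymetrix's scanner software, is named in the submitters' processing notes, and no scaling target is given in the sources used here. The deposited intensities of the 4 arrays had trimmed means (2% at each end) of 39.3, 40.7, 36.7 and 55.6, which differ by a ratio of 1.52. A rule set before the data were examined kept the authors' scaling only if these differed by no more than 10 percent, so quantile normalization was used. The median signal was 4.90 to 6.50 across the arrays as deposited, and 30.9% to 35.2% of probe sets had a signal of 16 or more, so many probe sets are dim.

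The table has 57381 probe sets. The 187 control probe sets were left out. Values were quantile normalised, then put on the log2(intensity + 16) scale, which understates the change of dim probe sets. Probe sets at or above the 40th percentile of mean log2 value were kept, leaving 34316. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), with group as the only term and Benjamini-Hochberg adjustment at 0.05. Differences are high minus low grain number, SE is limma's moderated standard error, and intensities are quantile normalised with the SD of 2 arrays. The labels call the arrays biological replications and do not say what the replications share, such as the same lines. The p-values measure only the spread between the 2 arrays within a group. They do not cover how other lines would differ, so calls cannot be extended from these bulks to high and low grain number at large. Each bulk holds 10 lines, whose individual values are not seen.

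Probe sets were named through a table pairing them with genes, which can be old, and symbols were updated from NCBI's gene table (assembly named in that table as ASM3414082v1). Of the probe sets other than controls, 22436 were paired with 1 gene, 95 with several and 34663 with none. None was named from a probe set with several genes. Since the files name no genome build, no coordinates are given, and the gene table was used only for names and for which genes neighbour each other. Where a gene had several probe sets, the one with the highest mean was used in lists and in the neighbour count. Of all 134 genes past the threshold, 41 had several tested probe sets. Of those 41, 6 had probe sets of both signs and 0 passed in both directions.

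Gene lists were tested with camera (preset correlation 0.01, and estimated) and fry, where at least 5 members were measured. With an estimated correlation, camera takes its degrees of freedom from the number of arrays and not of genes, so few lists can pass. Of the lists planned before the data were examined, 5 name their members. These name 89 members, of which 55 were matched by symbol and are on the array. The planned lists that search gene descriptions were not run, because the gene table has no descriptions. They were replaced by 39 lists that search gene symbols, written after the gene table was seen but before any group comparison was made. A symbol can stand for genes of other families, so some list members do not do what the list's name says. After the list results were seen, 3 of these patterns (heat shock protein, KNOX and aquaporin) were found to take in such genes. The patterns as first written stayed the main ones, and narrowed forms of those 3 were run as an added alternative. Other patterns took in such genes too but were not narrowed. The SPL list shares 1 gene with the heat shock factor list. The chitinase and pathogenesis-related list holds NPR1 (LOC4327315) through a synonym, PR2.

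For the neighbour count, same-sign pairs within 10 measured genes were counted among the 200 genes with the smallest p, against 10000 random draws. The rule for named genes took up to 12 genes per direction with the largest difference past the threshold, the 2 members per list and direction with the smallest p (of which fewer may be named), chosen grain number genes, the densest stretch of neighbours, and at most 2 unnamed probe sets per direction. Genes named outside it are said to be chosen after their values were seen.

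The steps were tested on simulated data for the comparison of 2 against 2 arrays, with 200 changed probe sets among 34316. With each probe set's spread set to its observed value, which takes chance differences in spread as real, 0% of the 2-fold and 0% of the 4-fold changes were called. With spreads moderated over probe sets, a version added after that result, 56% of the 2-fold and 83% of the 4-fold changes were called, with 11 false calls among 150. The share called therefore depends on how uneven the true spreads are. Limma's prior degrees of freedom were 1.89 in the first simulation, 36.5 in the second and 9.05 in the real data. The sign was right for all changed probe sets in both simulations.

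Alternatives covered the scaling, the filter, the pseudocount, the variance trend, the replicate numbers as a block, each array left out, the fold threshold, the probe sets of a gene, the correlation in camera and the settings of the neighbour count.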

Results

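Gene expression was measured with the Affymetrix rice array in panicle primordia of Oryza sativa (Indica Group), taken at the stage the submitters number 0. Each RNA sample was a bulk of 10 recombinant inbred lines (RILs), which are lines fixed by repeated selfing after a cross. One kind of bulk came from lines with a high grain number per panicle and the other from lines with a low grain number. Each kind was measured in 2 biological replications, giving 4 arrays. The arrays were similar, with Pearson correlations between 0.969 and 0.981 across tested probe sets, which are not independent replicates. The 2 low arrays were the most alike (0.981). The 2 high arrays (0.974) were no more alike than high grain number replicate 2 and low grain number replicate 2 (0.975). The number of arrays limits the precision, because the spread within a group rests on 2 values. The median SD of the 2 arrays of a group was 0.156 on the log2 scale for high grain number and 0.137 for low grain number. The low grain number replicate 2 array was the brightest as deposited, with a trimmed mean signal of 55.6 against 36.7 to 40.7 on the others.

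The comparison asked which genes differ in expression in young panicles between lines with many and with few grains. Most of the genes past the threshold were lower in the high grain number bulks, and small heat shock protein and secondary cell wall genes were among them. RTS (LOC4326940), a gene of the anther tapetum, had an intensity of 388 ± 232 (SD, n = 2) in the low bulks and of 1.2 ± 0.46 in the high bulks, a log2 difference of -4.42 ± 0.33 (SE, limma adjusted p = 2.58e-04). OsDOS (LOC4327304), a zinc finger protein that delays leaf senescence, had 1625 ± 31.6 against 236.0 ± 16.9, a log2 difference of -2.70 ± 0.17 (limma adjusted p = 7.52e-05). LOC4337241 had the largest increase among probe sets with 1 gene past the threshold, from 50.1 ± 29.0 in the low bulks to 522 ± 42.0 in the high bulks (log2 difference 3.09 ± 0.28, limma adjusted p = 6.15e-04).

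In all, 195 of 34316 tested probe sets passed an adjusted p of 0.05 (limma, two-sided, Benjamini-Hochberg). Of these, 53 were higher and 142 lower in the high grain number bulks, so 27.2% were higher. Of them, 139 are paired with 1 gene and stand for 134 genes, 31 higher and 103 lower, and the other 56 have no single gene here. Under the authors' scaling as deposited, 37 were higher and 233 lower (13.7% higher), and after median centring 59 were higher and 332 lower (15.1% higher). With no filter on dim probe sets, 0 probe sets passed (limma, 3849 at an unadjusted p under 0.05, smallest adjusted p 0.0743). Leaving out the high grain number replicate 1 array left 90, leaving out low grain number replicate 1 left 54 and leaving out low grain number replicate 2 left 53.

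By size alone, 347 probe sets differed by 2-fold or more with no overlap between the groups, 87 higher and 260 lower in the high grain number bulks. Across the tested probe sets 37.1% had no overlap, where chance gives 2 of 6 orderings, and 52.7% of these were higher in the high grain number bulks. At an unadjusted p under 0.05, 46.7% of 2828 were higher.

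Beyond RTS, OsDOS and HSP18.1 (-3.07 ± 0.23, described with its group), the named genes with the largest decreases were LOC4349197 (log2 difference -3.63 ± 0.25), LOC9270848 (-3.41 ± 0.20), LOC4337901 (-3.12 ± 0.51), LOC4326388 (-2.88 ± 0.45), LOC4341282 (-2.78 ± 0.23), LOC4347323 (-2.74 ± 0.37), LOC4346676 (-2.66 ± 0.38) and LOC9268371 (-2.57 ± 0.31). CHS1 (LOC4350636), a chalcone synthase of flavonoid synthesis, had a log2 difference of -2.58 ± 0.36. The named increases were LOC4326298 (2.23 ± 0.36), IRL3 (LOC4336157, an isoflavone reductase-like gene, 2.01 ± 0.20), LOC4342991 (2.00 ± 0.27), LOC9270481 (1.91 ± 0.20), LOC4341223 (1.86 ± 0.24), LOC4325989 (1.79 ± 0.21), LOC4333210 (1.77 ± 0.21), LOC4333113 (1.69 ± 0.21), LOC4342861 (1.52 ± 0.27) and LOC4336164 (1.49 ± 0.24). Among probe sets not paired with a gene here, the 2 that fell most had log2 differences of -4.41 ± 0.25 and -2.78 ± 0.22, and the 2 that rose most had 1.88 ± 0.27 and 1.79 ± 0.23. All of these passed the limma test at an adjusted p of 0.05. LOC4336164 did not pass under the deposited scaling (adjusted p = 0.192) or after median centring (0.0503). LOC4342861 and LOC4337901 did not pass with the filter at the 60th percentile (0.0661 and 0.0559), and these 2 and LOC4326388 did not with log2(value + 1) (0.157, 0.0659 and 0.0682). With log2(value + 64), LOC4342861 did not pass either (limma adjusted p = 0.0547). Of the 45 probe sets of the text past the threshold, 14 lost it without high grain number replicate 1, 3 without high grain number replicate 2, 24 without low grain number replicate 1 and 24 without low grain number replicate 2.

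**Figure D1:**
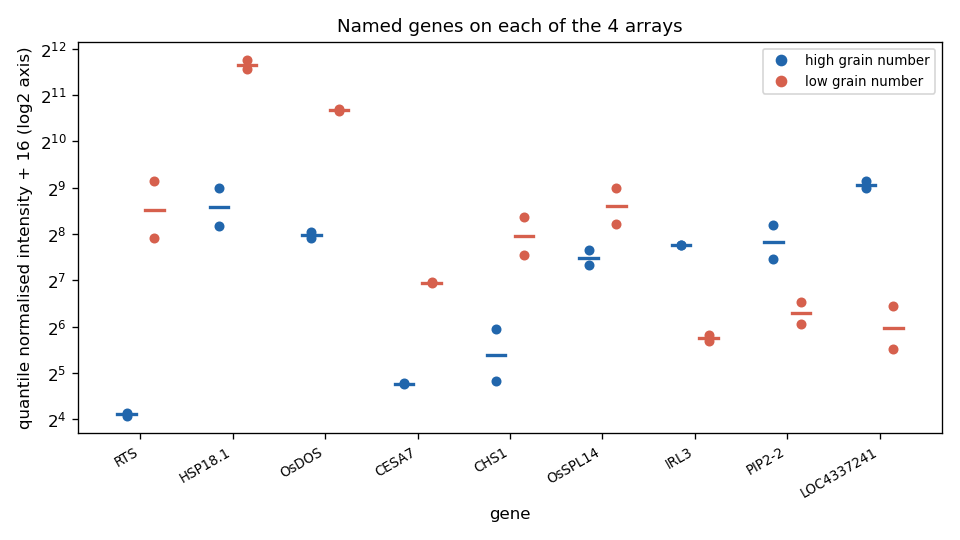
Quantile normalised intensity plus 16 on each array (log2 axis) for 9 named genes. Points are arrays, 2 per group, and bars are the geometric mean of each group. RTS lies near the floor on both high grain number arrays, OsSPL14 did not pass the threshold (adjusted p = 0.122), and LOC4337241, IRL3 and PIP2-2 are higher in the high grain number bulks.

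All 24 measured members of the heat shock protein list, 23 heat shock protein genes and a transcription factor held through a synonym, had a negative difference, with a median of -1.02 on the log2 scale (2.03-fold lower in the high grain number bulks). The camera test gave an adjusted p of 2.16e-23 with the preset correlation of 0.01. The correlation estimated between the members was 0.209, so the preset one overstates the evidence for this list. With the estimated correlation the camera adjusted p was 0.751, and fry gave an adjusted p of 0.353. Of the 24 members, 5 passed the threshold over all probe sets, and 16 did when adjusted over the list alone. HSP18.1 (LOC4332361) had an intensity of 383 ± 153 (SD, n = 2) in the high bulks and of 3223 ± 329.5 in the low bulks, a log2 difference of -3.07 ± 0.23. The log2 difference was -2.40 ± 0.31 for HSP17.8 (LOC4330496), -2.34 ± 0.33 for HSP26.7 (LOC4332237) and -1.60 ± 0.22 for HSP101 (LOC4339343), a protein disaggregase. The fifth was that transcription factor, HSFA2A (LOC4334080, -2.18 ± 0.32), which the list holds through an older synonym, HSP2. HSP81-1, HSP81-2 and HSP81-3, which are HSP90 genes, were near 0 (-0.10 ± 0.13, -0.02 ± 0.13 and -0.01 ± 0.12) and did not pass. HSP81-2 and HSP81-3 changed sign when an array was left out. HSP26.7 and HSP101 were chosen after their values were seen, as called members of the list. The actin 3' to 5' signal ratio, a sign of RNA quality, was 33.3 and 36.9 on the high arrays and 42.2 and 47.8 on the low arrays. With 2 arrays per group, such a separation often arises by chance. The GAPDH ratio, from signals of 10 or less, was 1.32 and 9.09 on the high arrays and 0.4 and 7 on the low arrays, without separation.

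Heat shock factor genes, which encode the transcription factors of that response, had a median log2 difference of -0.32 over 19 members, of which 16 were negative. Only HSFA2A passed over all probe sets, and 6 did when adjusted over the list alone. HSFA3 (LOC4329526) had -1.29 ± 0.27 (limma adjusted p = 0.0823), and it passed under the deposited scaling (0.0190), after median centring (0.00271) and without high grain number replicate 2 (0.0359). The camera adjusted p was 9.04e-06 with a preset correlation and the adjusted p was 0.751 with an estimated correlation. The actin 3' to 5' ratio stood higher on both low arrays here too.

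**Figure D2:**
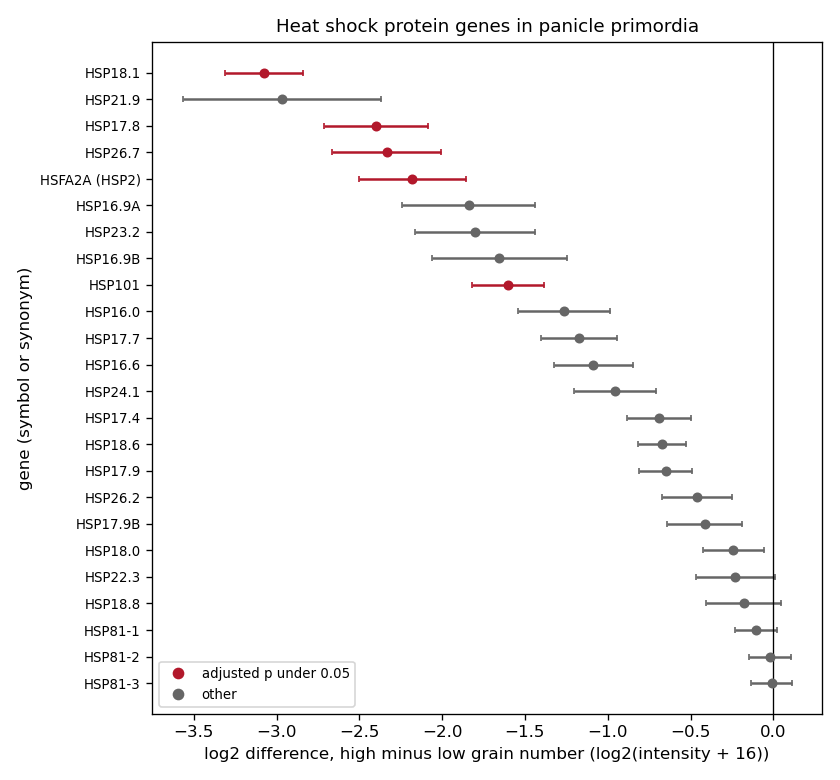
Log2 difference, high minus low grain number, for each of the 24 measured members of the heat shock protein list. Points are limma estimates and bars their standard errors, on the log2(intensity + 16) scale, and red marks the 5 members past adjusted p 0.05. Every point lies below 0, and the HSP90 genes at the bottom lie close to it.

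Of 17 measured laccase, cinnamyl alcohol dehydrogenase (CAD) and secondary wall genes, 4 passed the threshold, all lower in the high grain number bulks, and 5 did when adjusted over the list alone. The other 13 did not pass, and 6 of the 17 had a positive difference. CESA7 (LOC4348853), a cellulose synthase of secondary walls, had an intensity of 11.2 ± 0.41 (SD, n = 2) in the high bulks and of 108 ± 2.47 in the low bulks, a log2 difference of -2.19 ± 0.20. CESA4 (LOC4324625), another secondary wall cellulose synthase, had -1.76 ± 0.25. BC1 (LOC4333114), a COBRA-like protein whose loss makes culms brittle, had -1.68 ± 0.27, and the laccase LAC10 (LOC4332400) had -1.28 ± 0.25. With log2(value + 1) neither BC1 nor LAC10 passed (limma adjusted p = 0.0566 and 0.0903), nor did LAC10 with the filter at the 60th percentile (0.0782). CESA9 (LOC4347093) did not pass over all probe sets (-0.83 ± 0.21, limma adjusted p = 0.173), but did after median centring (0.0212). BC1 and LAC10 were chosen after their values were seen. The list's median was -0.13 and its mean -0.49. The median was -0.30 without high grain number replicate 1, -0.27 without high grain number replicate 2, -0.30 without low grain number replicate 1 and -0.26 under the deposited scaling. The camera adjusted p was 2.21e-04 with a preset correlation and the adjusted p was 0.751 with an estimated correlation. The list serves as a marker of stem tissue, and the actin ratio given above differed in the same samples.

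Genes of inflorescence branching and grain number, the list nearest to the trait, had 0 of 9 measured members past the threshold (limma, 1 at an unadjusted p under 0.05). That member was OsSPL14 (LOC4345998), a transcription factor that promotes panicle branching. Its intensity was 165 ± 28.6 (SD, n = 2) in the high bulks and 387 ± 148 in the low bulks, a log2 difference of -1.12 ± 0.26 (limma adjusted p = 0.122, and 0.0114 adjusted over the list alone). RFL (LOC4336857) had 0.51 ± 0.32, LAX1 (LOC4327431) -0.12 ± 0.20 and Hd1 (LOC4340746) -0.13 ± 0.19. LAX1 had an intensity of 10.7 in the high bulks and 13.1 in the low bulks, and Hd1 had 8.4 and 10.7. These lie below the 16 added to each value, which pulls their differences towards 0. RFL was at 177.6 on the high grain number replicate 2 array and at 69.2 to 77.0 on the others, and without that array its difference was -0.082. LAX1 was at 0.027 without low grain number replicate 2. The list's median was 0.03 (camera adjusted p = 0.907). Most of the genes that the list names, Gn1a, DEP1, Ghd7, TAW1 and APO1 among them, were not analysed here. FZP and Ghd8 were too dim to be tested. The list's result therefore covers only a minority of its genes.

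Meristem identity genes had 0 of 15 members past the threshold (limma, 1 at an unadjusted p under 0.05), with a median of -0.03 (camera adjusted p = 0.907). OsMADS22 (LOC4330805) came closest, with a log2 difference of -0.92 ± 0.26 (limma adjusted p = 0.240). Later floral organ genes, a marker of older floret tissue, had 0 of 12 past the threshold (limma, 0 at an unadjusted p under 0.05), a median of 0.03 and a camera adjusted p of 0.920. OsMADS58 (LOC4338067) in that list had 0.19 ± 0.21. Gibberellin genes had 0 of 5 past the threshold (limma, 0 at an unadjusted p under 0.05), with a median of -0.03 (camera adjusted p = 0.585). That median was -0.21 without high grain number replicate 1, -0.11 without high grain number replicate 2, -0.19 under the deposited scaling and -0.19 after median centring, with no call.

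Cytokinin turnover and response genes had 10 of 11 members with a positive difference, and 0 passed the threshold over all probe sets or when adjusted over the list alone (limma, 1 at an unadjusted p under 0.05). CKX3 (LOC4348932), which degrades cytokinin, had 0.47 ± 0.20, and the response regulators OsRR1 (LOC4335937) and OsRR4 (LOC4325747) had 0.41 ± 0.20 and 0.33 ± 0.20. The list's median was 0.22 (camera adjusted p = 0.146), and it was 0.058 under the deposited scaling and 0.061 after median centring.

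Of the 44 gene lists tested, 4 passed a camera adjusted p of 0.05 with a preset correlation, all of them lower in the high grain number bulks, and 0 passed with an estimated correlation. With fry, which tests whether a list moves on balance one way, 0 lists passed (smallest adjusted p 0.353). The fourth was the chitinase and pathogenesis-related list, whose 7 members were all negative (median -0.35). Of them, 0 passed the threshold (limma, 2 at an unadjusted p under 0.05). Those 2 were dim. Cht1 (LOC4338719) had an intensity of 1.78 in the high bulks and 9.15 in the low bulks. NPR1 (LOC4327315), held through its synonym PR2, had 11.9 and 22.0. The list's camera adjusted p was 0.0252 with a preset correlation and 0.820 with an estimated correlation. Leaving out high grain number replicate 1 or low grain number replicate 2 ended that call (adjusted p = 0.0866 and 0.494).

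Bulks of selected lines can share stretches of a parent's genome, so the order of the differing genes was examined. Among the 200 genes with the smallest p, 28 pairs lay within 10 measured genes of each other with the same sign, where 10000 random draws gave a mean of 12.5 and a central range of 6 to 20 (one-sided permutation p = 3.00e-04). With pairs 1 or 2 genes apart left out, an alternative chosen after seeing the data, 16 pairs remained (one-sided permutation p = 0.0459). That count lay within the central range of 4 to 17. The densest stretch held LOC4337113, LOC4337127 and LOC4337133, with log2 differences of -1.09 ± 0.25, -2.40 ± 0.26 and -0.98 ± 0.21. Of these, LOC4337127 passed the threshold (limma adjusted p = 0.00209), and LOC4337113 did under the deposited scaling (0.00344) and after median centring (3.53e-04).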

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

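The tests of this part chosen after the data were seen include the neighbour counts with signs kept (at either distance) and with close pairs left out, and the narrowed symbol patterns. Most probe sets are dim, and how far the signal over background limits each result was not tested. The count past the threshold (195, 53 higher and 142 lower) depended on the filter: with none it was 0 (0 higher, 0 lower), where limma's prior degrees of freedom were 3.59 against 9.05 and 57194 probe sets were tested. It was 391 (332 lower) after median centring and 128 (91 lower) with log2(value + 1), and 233 were lower with the deposited scaling. The cause was not tested. Of the main calls, 150 were shared with the deposited scaling, 176 with median centring and 128 with log2(value + 1). Without 1 array the count ranged from 53 to 229, with 7 to 45 higher and 43 to 184 lower; an array left alone in its group is assumed to vary like the other group. The count by size (347, 87 higher and 260 lower) was 3085 (1415 higher, 1670 lower) with log2(value + 1) and 135 (24 higher, 111 lower) with log2(value + 64). It was 1381 (556 higher, 825 lower) at 1.5-fold and 101 (14 higher, 87 lower) at 3-fold, as those thresholds imply. The higher part was 54 with the deposited scaling and 55 after median centring. Without 1 array it ranged from 380 to 611 (113 to 151 higher, 234 to 460 lower).

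The number of lists past the threshold was 0 with an estimated correlation, where the medians are the same by construction: -1.02 for heat shock proteins, -0.32 for heat shock factors, -0.13 for secondary wall genes and -0.35 for chitinases. It was 5 with the narrowed patterns, which were tested with the preset correlation only. There the aquaporin list passed (median 0.31 over 21 genes, camera adjusted p = 0.0399, against 0.16 over 26 genes and 0.236), and heat shock proteins had a median of -0.96 over 23 genes. With an estimated correlation the aquaporin list of 26 genes had a camera adjusted p of 0.820. Secondary wall genes had a median of -0.46 and heat shock factors of -0.65 with log2(value + 1), and of -0.062 and -0.13 with log2(value + 64), and both stayed past the threshold. Chitinases had a median of -0.98 and missed the threshold with log2(value + 1), and had -0.12 with log2(value + 64). The symbol list of cytokinin genes passed with no filter (median 0.18), without the trend (0.21) and with the mean of all probe sets of a gene (0.21). The planned cytokinin list passed with the mean of all probe sets (0.22), while its median was 0.058 with the deposited scaling, 0.061 after median centring and 0.12 with log2(value + 64). Later floral organ genes had a median of -0.12 with the deposited scaling and of -0.12 after median centring, where the median of all tested probe sets moved from 0.01 to -0.07 in each case. Without 1 array, medians ranged from -0.033 to 0.11 for later floral organ genes, -0.082 to 0.16 for meristem genes, -0.081 to 0.23 for inflorescence genes, -0.30 to -0.10 for secondary wall genes, -0.21 to -0.031 for gibberellin genes and -0.44 to -0.22 for chitinases. The cause was not tested. Without 1 array, log2 differences ranged from -0.066 to 0.028 for HSP81-2, -0.053 to 0.035 for HSP81-3, -0.082 to 1.10 for RFL and -0.27 to 0.027 for LAX1. Of 45 named genes past the threshold, 45 lost it with no filter, 4 with the deposited scaling (PIP2-2, H2B.10, EME1 and LOC4336164, all increases), 32 when some array was left out, and 0 changed sign under any setting. The neighbour count had a one-sided p from 1e-04, the smallest the draws can give, to 0.0459 over the settings run. The highest was with pairs 1 or 2 genes apart left out, where the 16 pairs lay within the central range of 4 to 17. For pairs 11 to 50 genes apart with the signs kept, p was 0.0540.

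The replicate numbers did not mark a stated shared batch. Between the groups, the difference of replicates 1 and 2 correlated at 0.111 over probe sets, with only 2 pairs, so the numbers were not taken as pairing. With the replicate block, 654 probe sets passed (189 higher, 465 lower), and 4 lists did. Of the named genes that had missed the threshold, it was passed with the block by OsSPL14 (limma adjusted p = 0.00572), OsMADS22 (0.0234), HSFA3 (0.00378), LOC4337113 (0.00557) and LOC4337133 (0.00948).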

Other observations

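The tests of neighbour co-expression and of other splits of the arrays, the neighbour counts with signs kept or close pairs left out, and the narrowed symbol lists were chosen after the result was seen. Other called genes stood outside the groups above, of which PRX74, EGY3, SAT1, H2B.10 and EME1 were chosen after their values were seen. Of 53 measured PP2C protein phosphatase genes, 2 passed the threshold, PP2C68 (-1.43 ± 0.22) and PP2C30 (LOC4332374, -1.22 ± 0.22), both of abscisic acid signalling. PP2C30 did not pass with the filter at the 60th percentile (limma adjusted p = 0.0632), with log2(value + 1) (0.0616) or without the variance trend (0.0582). The other 51 did not pass, 26 of the 53 were positive, and the median was -0.00101. The calmodulin-like gene CML15 (LOC4338633) had -1.64 ± 0.26, the class III peroxidase gene PRX74 (LOC4339222) -2.07 ± 0.25, EGY3 (LOC4333985) -1.89 ± 0.29 and the serine acetyltransferase gene SAT1 (LOC4324655) -1.53 ± 0.20. Higher in the high bulks were the histone gene H2B.10 (LOC4324495), with 1.35 ± 0.18, and EME1 (LOC4337213), a subunit of a DNA junction endonuclease, with 1.43 ± 0.22. Neither passed under the deposited scaling (limma adjusted p = 0.171 and 0.248), nor did EME1 after median centring (0.0747). The water channel gene PIP2-2 (LOC4330049) had 1.52 ± 0.27 (limma adjusted p = 0.0358, and 0.0965 under the deposited scaling, 0.0640 with the filter at the 60th percentile and 0.0607 with log2(value + 1)). Its list had 5 members higher and 3 lower when adjusted over the list alone, but 2 of the 3, HSFA2D and LOC4348646, carry heat shock factor names and are in that list too. The narrowed list of 21 genes had a median of 0.31 (camera adjusted p = 0.0399 with a preset correlation, the only way it was tested). The list of 26 genes as first written had a camera adjusted p of 0.236 with a preset and 0.820 with an estimated correlation, and 0.473 with fry.

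The lower heat shock protein genes did not rest on the normalization between arrays, since the list's median was -1.16 under the deposited scaling, or on 1 array, since the highest median with an array left out was -0.73. Stress or wounding when the tissue was taken stays open. Jasmonate genes, used as its sign, had a camera p of 0.402 and a median of 0.05, which neither shows nor excludes it. Their members moved both ways, with 12 negative and 13 positive, and 4 had an unadjusted limma p under 0.05. JAZ13 (LOC4348531) had -1.13 ± 0.25 and passed when adjusted over the list alone, while JAZ1 (LOC4337240) had 0.37 ± 0.16. The mixed form of fry, which lets members move either way, gave an unadjusted p of 5.75e-04. The actin ratio also stood apart between the groups, though on few arrays, while the GAPDH ratio, from dim signals, did not. Genetic differences between the bulks were not tested apart from handling.

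The lower secondary wall genes and RTS may come from tissue that differed in age or makeup between the bulks. For more advanced florets in the low bulks, later floral organ genes gave a camera p of 0.810. For green leaf tissue, photosynthesis genes gave a camera p of 0.637. Members of both lists went both ways, so neither explanation is excluded, and a difference set by the lines' genotypes was not tested.

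The excess of same-sign neighbours did not come from the unequal numbers of higher and lower genes alone, since 28 pairs exceeded the upper end, 24, of the central range of draws with the signs kept. Tandem copies and shared probe sets may account for part of it, but were not looked at directly. With pairs 1 or 2 genes apart left out, 16 pairs remained, within the central range of 4 to 17 (one-sided permutation p = 0.0459). Leaving out close pairs also removes close neighbours of any other kind, so it cannot tell such copies apart from them. Parental segments shared within a bulk are not settled, because 73 pairs lay 11 to 50 genes apart, above the range of 36 to 64 from plain draws but within that of 45 to 76 with the signs kept. Co-expression of neighbours whatever the grain number stays open, since the other splits gave at most 14 pairs but hold 0 called probe sets.

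The 4 arrays make 3 splits into groups of 2, too few for a share under 0.05. The real split, 1 of the 3, called 195 probe sets and the highest other called 0 (limma, 1665 and 920 probe sets at an unadjusted p under 0.05 in the other 2). Each group of the other 2 holds both a high and a low array. Any difference between high and low then adds to the spread within a group and lowers the calls, so the counts are not a fair comparison.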
